A study of Homo sapiens with 24 samples.

How the data were processed

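The data were 24 Affymetrix PrimeView arrays of the renal cell carcinoma lines Caki-1 and 769-P, treated with DMSO or with 1 µM dasatinib for 6, 12 or 24 h, with 3 arrays in each of 8 groups. Per the labels' protocols, cells were kept at 37 °C in 5% CO2, RNA was extracted with TRIZOL and cleaned on columns with DNase treatment, and biotin-labelled cRNA was made from the 3' end. Groups were read from the labels alone. The labels call the arrays of a group biological replicates and do not say whether these were cultured or treated on separate days. No time is given for the DMSO arrays, so the same 3 DMSO arrays of a line were the control at 6, 12 and 24 h, and comparisons within a line share them.

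The deposited values were log2 signals, 1 per probe set and array, made by the authors before deposit. The submitters' processing notes name MAS5 without a version or settings. The values ran from 2.8 to 15.19, and the array medians differed by 0.076, so the arrays had been brought to a common level before deposit, by a method not given in the sources used here. PrimeView carries perfect-match probes only, so how MAS5 was applied is unclear. Raw intensities were not used here. A high level of a probe set does not rank its gene against other genes, because probe sets differ in affinity.

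Of 49395 probe sets, 102 were array controls. The manufacturer's annotation on the platform record, dated 2021, was joined to the given gene table by Entrez identifier, which gave 44988 probe sets that name exactly 1 gene, 1832 that name several and 2473 without an entry, for 18132 genes. Each gene was read from its brightest probe set among those with exactly 1 gene, by mean over the arrays. Within a line, genes entered the tests if their mean over its 12 arrays lay above the 40th percentile of the means of all probe sets, 5.379 in Caki-1 and 5.361 in 769-P. For the tests over all 24 arrays they had to pass in at least 1 line. Gene places are from the RefSeq annotation of GRCh38.p14.

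Moderated t tests were run in limma 3.58.1 under R 4.3.3 with an intensity trend and a group-means design. The 6 comparisons of dasatinib with DMSO and the comparisons of 24 h with 6 h used the 12 arrays of the line (8 residual degrees of freedom). The interaction test, the Caki-1 change minus the 769-P change, and the comparison of the lines under DMSO used all 24 arrays (16 residual degrees of freedom). P-values were adjusted over all genes of a comparison by the Benjamini-Hochberg method, and genes under 0.05 were called. The median SE of a change was 0.100 in Caki-1, 0.105 in 769-P and 0.151 for a difference between the lines. Tables were read with the package data.table, version 1.17.8.

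Lists of genes were drawn up from general knowledge of the pathways, before the files were opened. They covered DNA replication and S phase, mitosis, p53 targets, FOXO targets and quiescence, YAP and TEAD targets, SRF and actin cytoskeleton, ERK pathway feedback and immediate-early genes, cholesterol biosynthesis, fatty acid synthesis, lysosome and autophagy, interferon-stimulated genes, ATF4 and unfolded protein response, hypoxia targets, NF-kB targets and inflammatory cytokines, extracellular matrix, TGF-beta targets, integrin and focal adhesion, receptor tyrosine kinases and ligands, dasatinib target kinases, apoptosis, ribosome biogenesis and MYC targets, cytosolic ribosomal proteins, oxidative phosphorylation, NRF2 targets, aryl hydrocarbon receptor targets, proximal tubule, epithelial, mesenchymal, heat shock, leukocyte markers and endothelial markers. Each list was tested with camera, which asks whether its genes rank higher or lower than the other genes tested, with its preset correlation of 0.01. Adjustment was over 31 lists and 6 comparisons together, and apart from that over the 2 comparisons of 24 h with 6 h, the 3 differences, and the DMSO comparison. Each test was repeated with the correlation estimated from the data and with fry, which says only whether the genes of a list move on balance one way.

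The design, the tests, the alternatives and the rule for the genes named were set before the data were examined. That rule took the 5 largest rises and falls of each comparison among called genes. Only for the comparisons of dasatinib with DMSO did the arrays of these genes also have to be free of overlap. There their higher group also had to lie above the median of all probe sets. For those comparisons the rule further took up to 4 called members of each list with the largest change (or the largest change where none was called). It also took 15 genes set by name for their ties to the drug. ANKRD1, one of these, lay under the filter and was not tested. Genes that were named after their values were seen are stated as such.

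The replicate numbers were tested as pairs by correlating the deviations of equally numbered arrays from their group means. Every pair was over 0.1 in 769-P at 6 h (0.11 to 0.36), at 24 h (0.12 to 0.17) and for 24 h against 6 h (0.10 to 0.19), so there the numbers were taken to pair the arrays, from the data and not from the labels. In the other comparisons at least 1 pair was not, with values from -0.05 to 0.31. The counts, changes, SE and p given come from fits without pairing, also where the numbers pair the arrays, unless a block is named. A block on the number was run as an alternative throughout. The other alternatives were quantile normalization, median centring, no filter and a 60th percentile filter, a floor at log2 4.27, a pseudocount of 41.2, the mean of the probe sets of a gene, every probe set on its own, no intensity trend, other arrays in the fit, a 2-fold threshold and leaving out each array in turn. Leaving out replicate 1 of 769-P at 24 h in fits that do not compare it was added after the data were seen.

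The pipeline was tested on simulated data in which 200 genes and the genes of a further list were shifted. At a log2 change of 1 it recovered 49 of 50 in Caki-1 and 49 of 50 in 769-P at 24 h, and 47 of 50 for the difference at 24 h. At 0.5 it recovered 39, 36 and 19 of 50, and of the genes left unchanged it called 4 of 12193, 11 of 12124 and 4 of 12634. The simulated noise was independent between genes, and far fewer genes were shifted than were called in the data. These rates may therefore not hold for the data. Protein, phosphorylation and cell growth were not measured, so kinase activity and growth itself are not reported.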

Results

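Gene expression was measured with Affymetrix PrimeView arrays, whose probe sets read mostly the 3' part of each transcript, in 2 human renal cell carcinoma lines. Caki-1 was derived from a skin metastasis and 769-P from a primary tumour. Cells of each line received the vehicle DMSO or dasatinib, an inhibitor of SRC family and ABL kinases, at 1 µM for 6, 12 or 24 h. The 24 arrays formed 8 groups with 3 arrays each. The labels call these arrays biological replicates and do not say how the cultures were separated. The DMSO arrays carried no time, so 1 DMSO group per line served as the control at each time, and hours of drug exposure could not be told apart from hours in culture. Array medians lay between 6.008 and 6.084 on the log2 scale, and arrays of the same group correlated at 0.9928 to 0.9975 across probe sets. With arrays, the number of replicates sets the precision. Values below are log2 changes of dasatinib against DMSO ± SE with n = 3 arrays in each group, unless stated otherwise, and "rose" or "fell" is used of genes with an adjusted p under 0.05 in limma.

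Dasatinib changed many genes in both lines, and more of them with each later time. In Caki-1, 1531 genes rose and 1742 fell at 6 h, 2991 rose and 3026 fell at 12 h, and 4085 rose and 3716 fell at 24 h, of 12423 tested. In 769-P, 2021 genes rose and 1795 fell at 6 h, 3078 rose and 2792 fell at 12 h, and 3841 rose and 3044 fell at 24 h, of 12354 tested. Changes of at least 2-fold were fewer, with 283, 761 and 1606 genes in Caki-1 and 459, 915 and 1549 genes in 769-P at the 3 times. Whether rises or falls were the more numerous depended on the scaling and on other choices of analysis in Caki-1 at 12 h and 24 h and in 769-P at 6 h and 12 h. Along the first principal component, which held 71.0% of the variance in Caki-1 and 63.6% in 769-P, the groups were ordered from DMSO through 6 h and 12 h to 24 h.

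**Figure D1:**
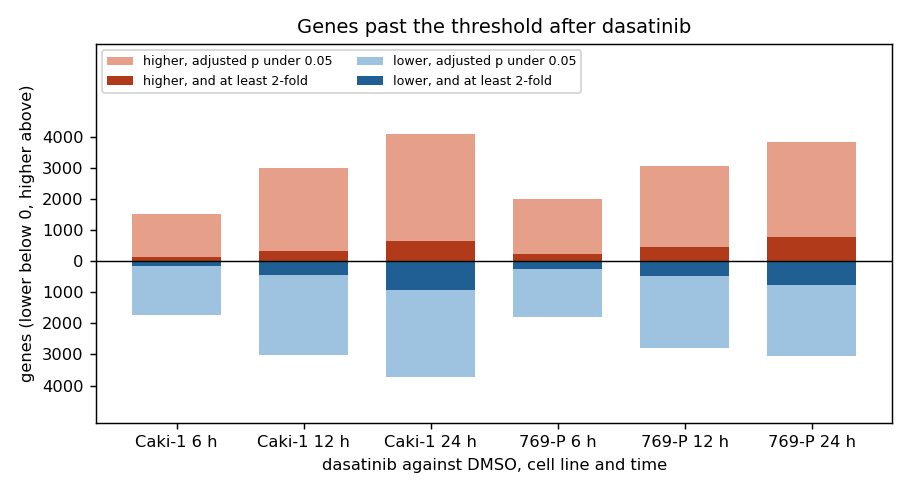
Number of genes past an adjusted p of 0.05 (y axis, genes) for each line and time of dasatinib against DMSO (x axis), with genes that rose drawn above 0 and genes that fell below 0, and darker bars for changes of at least 2-fold. The bars grow from 1531 and 1742 genes at 6 h in Caki-1 to 4085 and 3716 at 24 h, and from 2021 and 1795 to 3841 and 3044 in 769-P.

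The comparison of Caki-1 cells after 6 h of dasatinib with DMSO asked which genes moved first in that line. The steepest falls were in genes that YAP and TEAD activate: CCN2 (CTGF), a matricellular growth factor, fell by 3.60 ± 0.16, and CCN1 (CYR61), its close relative, fell by 3.54 ± 0.23. CCND1, the cyclin of the G1 phase, fell by 2.26 ± 0.17, FOSL1, a subunit of the AP-1 transcription factor, by 2.31 ± 0.14, and the receptor tyrosine kinase EPHA2 by 1.88 ± 0.11. Among the steepest rises were MT1F, a metal-binding metallothionein (3.55 ± 0.20), CDKN1C, an inhibitor of cyclin-dependent kinases also called p57 (2.76 ± 0.24), and the forkhead transcription factor FOXO1 (2.69 ± 0.09). In the GRCh38.p14 annotation CCN1 lies on chromosome 1 from 85580761 to 85583950, CCN2 on chromosome 6 from 131948176 to 131951372, and CDKN1C on chromosome 11 from 2883218 to 2885775.

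Of 25 YAP and TEAD target genes tested at 6 h in Caki-1, 14 fell and 2 rose, or 15 and 2 adjusted over the list alone. Their median change was -0.37, with a camera adjusted p = 3.4e-07 and an adjusted p = 0.108 with an estimated correlation. FOXO target and quiescence genes moved the other way, with 16 of 23 rising and 3 falling, the same counts adjusted over the list alone, a median of 0.68, adjusted p = 5.6e-07 and adjusted p = 0.157 with an estimated correlation. Among them KLHL24, a substrate receptor of a ubiquitin ligase, rose by 1.93 ± 0.19 and PDK4, a kinase that holds back pyruvate oxidation, by 4.28 ± 0.28. Ribosome biogenesis and MYC target genes fell in 23 of 28 cases, 26 adjusted over the list alone, with a median of -0.49, adjusted p = 9.3e-15 and adjusted p = 0.141 with an estimated correlation. The nucleolar proteins NOP16 and RRS1 fell by 1.39 ± 0.13 and 1.35 ± 0.11, and MYC itself by 1.13 ± 0.11. NRF2 target genes rose in 18 of 22 cases, 18 adjusted over the list alone, with a median of 0.56, adjusted p = 1.2e-11 and adjusted p = 0.108 with an estimated correlation. The cystine transporter SLC7A11 rose by 1.86 ± 0.20 and the aldo-keto reductase AKR1C1 by 1.96 ± 0.29. Lysosome and autophagy genes rose in 13 of 25 cases and none fell, 14 adjusted over the list alone, with a median of 0.25, adjusted p = 1.6e-05 and adjusted p = 0.151 with an estimated correlation. NPC1, which exports cholesterol from lysosomes, rose by 1.13 ± 0.14.

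Smaller movements were seen in 8 further groups at 6 h in Caki-1. DNA replication and S phase genes fell in 11 of 29 cases (11 adjusted over the list alone, median -0.24), with adjusted p = 3.7e-04 and adjusted p = 0.589 with an estimated correlation. The replication factor MCM10 fell by 1.13 ± 0.16. Mitosis genes rose in 7 of 29 cases (7 adjusted over the list alone, median 0.16), with adjusted p = 0.0116 and adjusted p = 0.773 with an estimated correlation. AURKA, a spindle kinase, rose by 0.70 ± 0.09. ERK pathway feedback and immediate-early genes split, with 11 of 27 falling and 5 rising (12 and 5 adjusted over the list alone, median -0.22), with adjusted p = 0.0285 and adjusted p = 0.596 with an estimated correlation. Within that group the AP-1 subunit JUN fell by 1.25 ± 0.16, while EGR1, an early growth response transcription factor, rose by 1.15 ± 0.14 and the ERK phosphatase DUSP6 by 0.88 ± 0.18. NF-kB target and inflammatory cytokine genes rose in 10 of 25 cases and fell in 3 (the same adjusted over the list alone, median 0.20), with adjusted p = 0.00526 and adjusted p = 0.473 with an estimated correlation. PTGS2, the inducible cyclooxygenase, rose by 2.001 ± 0.24 and IL6 by 1.01 ± 0.09. ATF4 and unfolded protein response genes rose in 10 of 28 cases (11 adjusted over the list alone, median 0.19), with adjusted p = 0.00173 and adjusted p = 0.332 with an estimated correlation. Heat shock genes fell in 5 of 16 cases (6 adjusted over the list alone, median -0.20), with adjusted p = 0.00894 and adjusted p = 0.268 with an estimated correlation. The co-chaperone DNAJB1 fell by 0.57 ± 0.08. Integrin and focal adhesion genes fell in 6 of 25 cases and 1 rose (the same adjusted over the list alone, median -0.11), with adjusted p = 0.031 and adjusted p = 0.19 with an estimated correlation. Of 7 aryl hydrocarbon receptor target genes 3 rose (3 adjusted over the list alone, median 0.20), with adjusted p = 0.013 and adjusted p = 0.431 with an estimated correlation. Among them the oxidase CYP1B1 rose by 1.30 ± 0.20. With the mean of all probe sets of a gene in place of its brightest, the changes of FOXO1, PDK4 and EGR1 were 1.58, 2.33 and 0.74. PDK4 under DMSO lay below the level of the filter on dim genes, so its fold is less certain than that of brighter genes.

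After 12 h of dasatinib in Caki-1 the largest falls included genes of the G1 to S transition. CCNE2, a cyclin that drives entry into S phase, fell by 3.18 ± 0.21, CDC6, which loads the replicative helicase, by 2.39 ± 0.15, and MCM10 by 2.38 ± 0.16. CCN1 and CCN2 stayed low, at -3.24 ± 0.23 and -2.98 ± 0.16. MT1F rose by 4.39 ± 0.20, AKR1C1 by 3.90 ± 0.29 and CDKN1C by 3.65 ± 0.24.

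DNA replication and S phase genes now fell in 28 of 29 cases in Caki-1 (28 adjusted over the list alone, median -1.31), with adjusted p = 8.7e-16 and adjusted p = 0.153 with an estimated correlation. Mitosis genes were divided, with 8 of 29 falling and 4 rising (6 and 4 adjusted over the list alone), and the list was not past the threshold. CDK1, the kinase that drives entry into mitosis, fell by 0.73 ± 0.12 and the spindle protein NUSAP1 rose by 0.53 ± 0.10. All 28 ribosome biogenesis and MYC target genes fell (28 adjusted over the list alone, median -1.08), with adjusted p = 2.1e-17 and adjusted p = 0.127 with an estimated correlation. LYAR, a nucleolar protein, fell by 1.79 ± 0.09 and UTP20, a ribosome assembly factor, by 1.74 ± 0.13. FOXO target and quiescence genes rose in 18 of 23 cases and 2 fell (the same adjusted over the list alone, median 0.99), with adjusted p = 2.8e-07 and adjusted p = 0.153 with an estimated correlation. YAP and TEAD target genes fell in 15 of 25 cases and 4 rose (16 and 4 adjusted over the list alone, median -0.37), with adjusted p = 1.4e-04 and adjusted p = 0.153 with an estimated correlation. Heat shock genes fell in 13 of 16 cases and 1 rose (the same adjusted over the list alone, median -0.43), with adjusted p = 9.4e-05 and adjusted p = 0.147 with an estimated correlation. HSPE1, a mitochondrial chaperonin, fell by 0.98 ± 0.09.

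Lysosome and autophagy genes rose in 17 of 25 cases at 12 h in Caki-1 and 1 fell (18 and 1 adjusted over the list alone, median 0.33), with adjusted p = 2.1e-05 and adjusted p = 0.151 with an estimated correlation. NPC1 rose by 1.62 ± 0.14 and WIPI1, which acts in autophagosome formation, by 1.43 ± 0.12. NRF2 target genes rose in 15 of 22 cases (15 adjusted over the list alone, median 0.43), with adjusted p = 3.3e-05 and adjusted p = 0.209 with an estimated correlation. Interferon-stimulated genes rose in 11 of 22 cases (11 adjusted over the list alone, median 0.27), with adjusted p = 0.00774 and adjusted p = 0.153 with an estimated correlation. IRF9, a subunit of the interferon-activated complex ISGF3, rose by 1.504 ± 0.11. Proximal tubule genes rose in 7 of 14 cases (7 adjusted over the list alone, median 0.29), with adjusted p = 0.04 and adjusted p = 0.203 with an estimated correlation. PAX8, a transcription factor of the renal epithelium, rose by 0.57 ± 0.07 and DPP4, a brush border peptidase, by 0.59 ± 0.08. NF-kB target and inflammatory cytokine genes rose in 13 of 25 cases and 4 fell (the same adjusted over the list alone, median 0.36), with adjusted p = 0.0456 and adjusted p = 0.643 with an estimated correlation.

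At 24 h of dasatinib in Caki-1 the cell division genes were low as a whole. All 29 mitosis genes tested fell (29 adjusted over the list alone, median -2.24), with adjusted p = 1.3e-15 and adjusted p = 0.271 with an estimated correlation. CDK1 fell by 2.74 ± 0.12, the spindle checkpoint kinase TTK by 2.72 ± 0.18 and the centromere histone CENPA by 2.69 ± 0.17. DNA replication and S phase genes fell in 28 of 29 cases (28 adjusted over the list alone, median -2.09), with adjusted p = 7.7e-17 and adjusted p = 0.151 with an estimated correlation. CCNE2 fell by 3.71 ± 0.21, CDC6 by 3.34 ± 0.15, MCM10 by 3.33 ± 0.16 and CDC45, a part of the replicative helicase, by 3.33 ± 0.18. Among the largest rises were MT1F (4.50 ± 0.20), RBP4, the plasma carrier of retinol (4.27 ± 0.22), and AKR1C1 (4.04 ± 0.29).

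The 28 ribosome biogenesis and MYC target genes again all fell at 24 h in Caki-1 (28 adjusted over the list alone, median -1.40), with adjusted p = 3.9e-14 and adjusted p = 0.145 with an estimated correlation. LYAR fell by 2.32 ± 0.09 and ODC1, the first enzyme of polyamine synthesis, by 2.09 ± 0.10. FOXO target and quiescence genes rose in 18 of 23 cases and 2 fell (18 and 3 adjusted over the list alone, median 1.43), with adjusted p = 2.0e-06 and adjusted p = 0.181 with an estimated correlation. CDKN1C rose by 3.61 ± 0.24 and KLHL24 by 3.38 ± 0.19. Lysosome and autophagy genes rose in 18 of 25 cases and 1 fell (the same adjusted over the list alone, median 0.58), with adjusted p = 3.3e-05 and adjusted p = 0.153 with an estimated correlation. The protease CTSF rose by 2.50 ± 0.24 and NPC1 by 1.97 ± 0.14. Heat shock genes fell in 12 of 16 cases and 2 rose (the same adjusted over the list alone, median -0.71), with adjusted p = 1.2e-04 and adjusted p = 0.151 with an estimated correlation. HSP90AA1, the inducible cytosolic HSP90, fell by 1.37 ± 0.12. YAP and TEAD target genes fell in 15 of 25 cases and rose in 5 (the same adjusted over the list alone, median -0.72), with adjusted p = 0.00778 and adjusted p = 0.28 with an estimated correlation. CCN1 fell by 2.34 ± 0.23, while IGFBP3, a binding protein of insulin-like growth factors, rose by 2.51 ± 0.12.

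NRF2 target genes rose in 14 of 22 cases at 24 h in Caki-1 and 3 fell (the same adjusted over the list alone, median 0.35), with adjusted p = 0.00835 and adjusted p = 0.455 with an estimated correlation. The haem-degrading enzyme HMOX1 rose by 1.99 ± 0.17. Proximal tubule genes rose in 7 of 14 cases (7 adjusted over the list alone, median 0.35), with adjusted p = 0.018 and adjusted p = 0.153 with an estimated correlation. DPP4 rose by 1.25 ± 0.08. NF-kB target and inflammatory cytokine genes rose in 14 of 25 cases and 1 fell (the same adjusted over the list alone, median 0.53), with adjusted p = 0.0175 and adjusted p = 0.576 with an estimated correlation. TNFAIP6, a hyaluronan-binding protein, rose by 1.80 ± 0.11 and IL6 by 1.26 ± 0.09. Interferon-stimulated genes rose in 12 of 22 cases and 1 fell (the same adjusted over the list alone, median 0.30), with adjusted p = 0.0456 and adjusted p = 0.266 with an estimated correlation. IFITM1 rose by 1.79 ± 0.20. The ERK pathway feedback and immediate-early genes were not past the threshold as a list at 12 h or 24 h in Caki-1. Within that list EGR1 rose by 3.22 ± 0.14 and DUSP6 by 1.496 ± 0.18 while FOSL1 fell by 3.003 ± 0.14 at 24 h. CDH1, the adhesion protein E-cadherin, rose by 3.90 ± 0.49. With the mean of all probe sets of a gene the changes of EGR1 and CDH1 at 24 h were 1.95 and 2.06.

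**Figure D2:**
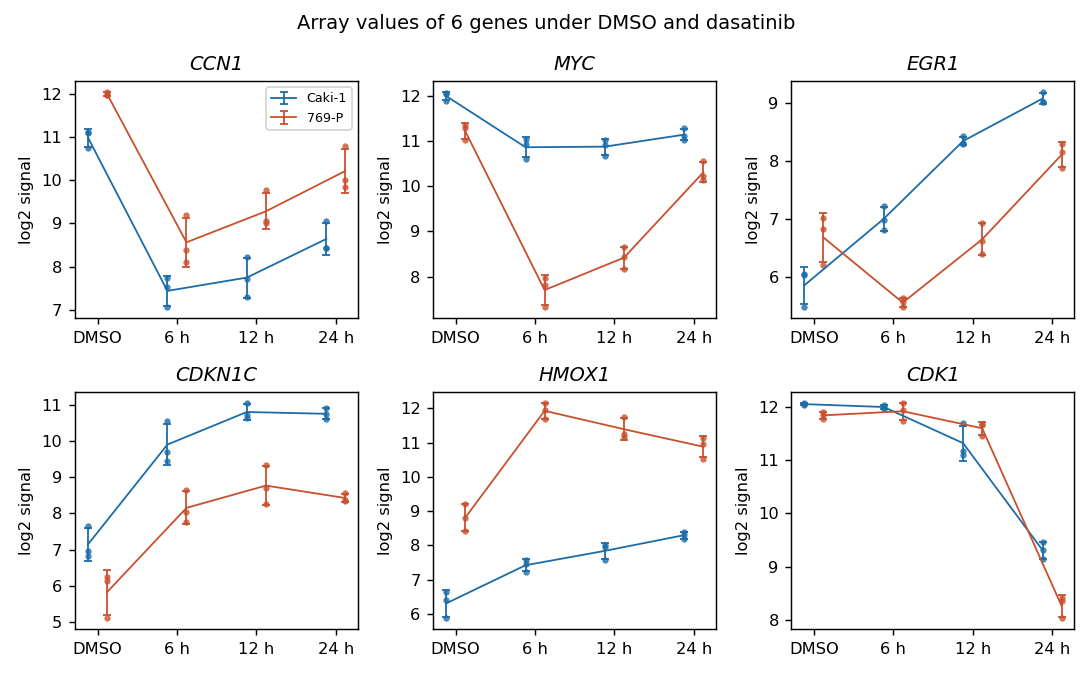
Array values on the log2 scale (y axis) of 6 genes under DMSO and after 6, 12 and 24 h of dasatinib (x axis) in Caki-1 and 769-P, with a point for each array and lines through group means with bars of ± 1 SD (n = 3). CCN1 changed by -3.54 in Caki-1 and -3.43 in 769-P at 6 h, EGR1 rose by 1.15 in Caki-1 at 6 h while it fell by 1.12 in 769-P, and CDK1 changed by -2.74 and -3.58 at 24 h.

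The comparison of 769-P cells after 6 h of dasatinib with DMSO asked the same question in the second line. MYC, a transcription factor that promotes growth, headed the falls at -3.51 ± 0.16, and CCN1 fell by 3.43 ± 0.27. HBEGF, a ligand of the EGF receptor, fell by 3.12 ± 0.21, CCND1 by 3.05 ± 0.14, FOSL1 by 3.02 ± 0.22 and EPHA2 by 2.40 ± 0.14. HMOX1, which degrades haem, rose by 3.12 ± 0.20, AKR1C1 by 2.48 ± 0.22 and CDKN1C by 2.33 ± 0.29. MYC lies on chromosome 8 from 127735434 to 127742951 and HMOX1 on chromosome 22 from 35381096 to 35394207.

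ERK pathway feedback and immediate-early genes fell in 19 of 26 cases at 6 h in 769-P and 2 rose (the same adjusted over the list alone, median -1.24), with adjusted p = 3.1e-13 and adjusted p = 0.0994 with an estimated correlation. EGR1 fell by 1.12 ± 0.18 there. This value, those of DUSP5 and SPRY2, and the differences of EGR1, MYC, DUSP5, SPRY2, MKI67 and COL5A2 given further on were chosen after they were seen. NRF2 target genes rose in 16 of 22 cases (17 adjusted over the list alone, median 0.50), with adjusted p = 9.9e-11, and this call held with an estimated correlation, at an adjusted p = 0.0141. GCLC, the enzyme that limits glutathione synthesis, rose by 1.82 ± 0.11. Ribosome biogenesis and MYC target genes fell in 21 of 28 cases and 1 rose (22 and 1 adjusted over the list alone, median -0.66), with adjusted p = 2.0e-13 and adjusted p = 0.132 with an estimated correlation. RRS1 fell by 1.93 ± 0.13 and WDR43, a processome component, by 1.75 ± 0.11. YAP and TEAD target genes fell in 15 of 22 cases (15 adjusted over the list alone, which added 1 rise, median -0.50), with adjusted p = 1.0e-08 and adjusted p = 0.0994 with an estimated correlation. FJX1, a secreted kinase-like protein on that list, fell by 2.17 ± 0.12. FOXO target and quiescence genes rose in 15 of 23 cases and 3 fell (16 and 3 adjusted over the list alone, median 0.90), with adjusted p = 6.3e-06 and adjusted p = 0.105 with an estimated correlation. DNA replication and S phase genes fell in 19 of 29 cases (20 adjusted over the list alone, median -0.37), with adjusted p = 7.5e-07 and adjusted p = 0.388 with an estimated correlation. CCNE2 fell by 1.72 ± 0.11. Lysosome and autophagy genes rose in 14 of 24 cases (15 adjusted over the list alone, median 0.27), with adjusted p = 1.1e-04 and adjusted p = 0.13 with an estimated correlation. NEU1, a lysosomal sialidase, rose by 0.70 ± 0.09.

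SRF and actin cytoskeleton genes fell in 13 of 27 cases at 6 h in 769-P (13 adjusted over the list alone, median -0.16), with adjusted p = 3.2e-04 and adjusted p = 0.241 with an estimated correlation. FHL2, a LIM-domain cofactor, fell by 1.78 ± 0.07. Integrin and focal adhesion genes fell in 12 of 26 cases and 2 rose (13 and 2 adjusted over the list alone, median -0.18), with adjusted p = 0.00109 and adjusted p = 0.0994 with an estimated correlation. The adaptor paxillin (PXN) fell by 0.67 ± 0.09. Heat shock genes fell in 9 of 16 cases and 1 rose (the same adjusted over the list alone, median -0.19), with adjusted p = 0.00631 and adjusted p = 0.252 with an estimated correlation. Cholesterol biosynthesis genes fell in 7 of 19 cases (7 adjusted over the list alone, median -0.18), with adjusted p = 0.014 and adjusted p = 0.712 with an estimated correlation. Squalene epoxidase (SQLE) fell by 1.34 ± 0.17 and MSMO1, a sterol oxidase, by 1.15 ± 0.17. Interferon-stimulated genes rose in 8 of 20 cases and 1 fell (the same adjusted over the list alone, median 0.15), with adjusted p = 0.0192 and adjusted p = 0.244 with an estimated correlation. The RNA sensor RIGI rose by 1.24 ± 0.11. Receptor tyrosine kinase and ligand genes fell in 13 of 24 cases and rose in 6 (the same adjusted over the list alone, median -0.26), with adjusted p = 0.0257 and adjusted p = 0.178 with an estimated correlation. ERBB3, a partner receptor of the EGF receptor family, rose by 2.70 ± 0.35. Mitosis genes rose in 11 of 29 cases and 1 fell (the same adjusted over the list alone, median 0.12), with adjusted p = 0.031 and adjusted p = 0.743 with an estimated correlation. The kinesin KIF20A rose by 0.64 ± 0.10. Oxidative phosphorylation genes rose in 8 of 27 cases and 1 fell (9 and 1 adjusted over the list alone, median 0.08), with adjusted p = 0.0376 and adjusted p = 0.53 with an estimated correlation. The replicate number, which paired the arrays in this comparison, brought as a block the aryl hydrocarbon receptor target genes, of which 3 of 7 rose, past the threshold (adjusted p = 0.0268, against an adjusted p = 0.0875 without it). Without the block it had an adjusted p = 0.511 with an estimated correlation. With the mean of all probe sets of a gene ERBB3 rose by 1.30 and EGR1 fell by 0.59.

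After 12 h of dasatinib in 769-P, AKR1C1 and AKR1C2, which encode neighbouring aldo-keto reductases, rose by 4.21 ± 0.22 and 4.13 ± 0.08, and MT1F rose by 3.73 ± 0.28. MYEOV, a gene near CCND1 that is often overexpressed in myeloma, fell by 4.30 ± 0.16, UBASH3B, a tyrosine phosphatase, by 4.10 ± 0.20, and CCNE2 fell by 3.72 ± 0.11. MYC, CCND1 and HBEGF stayed low, at -2.80 ± 0.16, -3.31 ± 0.14 and -3.31 ± 0.21.

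DNA replication and S phase genes fell in 27 of 29 cases at 12 h in 769-P (27 adjusted over the list alone, median -1.18), with adjusted p = 5.0e-17 and adjusted p = 0.151 with an estimated correlation. MCM10 fell by 2.97 ± 0.16. Mitosis genes went both ways, 9 of 29 falling and 8 rising (10 and 8 adjusted over the list alone), and were not past the threshold as a list. Ribosome biogenesis and MYC target genes fell in 25 of 28 cases and 1 rose (the same adjusted over the list alone, median -1.13), with adjusted p = 1.3e-13 and adjusted p = 0.132 with an estimated correlation. LYAR fell by 2.07 ± 0.11. NRF2 target genes rose in 17 of 22 cases (17 adjusted over the list alone, median 0.47), with adjusted p = 9.4e-08, and this call also held with an estimated correlation, at an adjusted p = 0.0236. HMOX1 rose by 2.58 ± 0.20. FOXO target and quiescence genes rose in 17 of 23 cases and 1 fell (the same adjusted over the list alone, median 1.18), with adjusted p = 2.0e-06 and adjusted p = 0.0994 with an estimated correlation. TXNIP, an inhibitor of thioredoxin, rose by 2.54 ± 0.28. Lysosome and autophagy genes rose in 19 of 24 cases (19 adjusted over the list alone, median 0.47), with adjusted p = 2.8e-07 and adjusted p = 0.0994 with an estimated correlation. NEU1 rose by 1.42 ± 0.09. YAP and TEAD target genes fell in 16 of 22 cases and 1 rose (the same adjusted over the list alone, median -0.73), with adjusted p = 9.7e-06 and adjusted p = 0.141 with an estimated correlation. CCN1 fell by 2.71 ± 0.27. ERK pathway feedback and immediate-early genes fell in 15 of 26 cases and 2 rose (15 and 3 adjusted over the list alone, median -0.61), with adjusted p = 2.5e-05 and adjusted p = 0.19 with an estimated correlation.

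SRF and actin cytoskeleton genes fell in 13 of 27 cases at 12 h in 769-P (13 adjusted over the list alone, median -0.34), with adjusted p = 1.4e-04 and adjusted p = 0.214 with an estimated correlation. Alpha-actinin (ACTN1) fell by 1.15 ± 0.11 and tropomyosin (TPM1) by 1.02 ± 0.05. Heat shock genes fell in 14 of 16 cases and 1 rose (the same adjusted over the list alone, median -0.54), with adjusted p = 1.1e-05 and adjusted p = 0.13 with an estimated correlation. FKBP4, a co-chaperone of HSP90, fell by 1.14 ± 0.08. The member that rose was CRYAB, a small heat shock protein, by 2.09 ± 0.13. Interferon-stimulated genes rose in 11 of 20 cases (11 adjusted over the list alone, median 0.50), with adjusted p = 0.00186 and adjusted p = 0.151 with an estimated correlation. IFIT1 rose by 1.67 ± 0.11 and RIGI by 1.57 ± 0.11. Integrin and focal adhesion genes fell in 14 of 26 cases and 3 rose (15 and 3 adjusted over the list alone, median -0.29), with adjusted p = 0.00806 and adjusted p = 0.108 with an estimated correlation. Integrin alpha 3 (ITGA3) fell by 1.92 ± 0.10. Oxidative phosphorylation genes rose in 16 of 27 cases and 2 fell (the same adjusted over the list alone, median 0.16), with adjusted p = 0.0139 and adjusted p = 0.431 with an estimated correlation. COX5B, a subunit of cytochrome c oxidase, rose by 0.46 ± 0.07. With the mean of all probe sets ITGA3 fell by 1.08 and AKR1C2 rose by 1.90, while CRYAB rose by 1.08.

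At 24 h of dasatinib in 769-P all 29 mitosis genes and all 29 DNA replication and S phase genes tested fell (29 and 29 adjusted over the list alone), with medians of -3.00 and -2.15. The proliferation marker MKI67 fell by 3.69 ± 0.08, CDK1 by 3.58 ± 0.10, and the checkpoint kinase BUB1B by 3.38 ± 0.10. GINS2, a part of the replicative helicase, fell by 3.68 ± 0.16 and MCM10 by 3.64 ± 0.16. These lists had an adjusted p = 7.9e-27 and an adjusted p = 3.2e-21, and with an estimated correlation an adjusted p = 0.0994 and an adjusted p = 0.131. AKR1C1 rose by 4.60 ± 0.22, SEMA5A, an axon guidance protein, by 4.10 ± 0.14 and KCNJ8, a potassium channel, by 3.90 ± 0.25. MYEOV fell by 4.47 ± 0.16 and MMP1, an interstitial collagenase, by 4.83 ± 0.20 to below the filter on dim genes. In replicate 1 of this group the ACTB control probe sets for the 3' and 5' ends differed by 4.07 on the log2 scale, against 2.67 to 3.22 on the other arrays. Those for GAPDH differed by 0.52 against 0.20 to 0.37, and both are signs of lower RNA quality.

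The remaining groups at 24 h in 769-P, all of which include that array, moved as follows. Ribosome biogenesis and MYC target genes fell in 24 of 28 cases and 1 rose (the same adjusted over the list alone, median -0.91), with adjusted p = 9.9e-10 and adjusted p = 0.153 with an estimated correlation. LYAR fell by 2.43 ± 0.11. Lysosome and autophagy genes rose in 19 of 24 cases (19 adjusted over the list alone, median 0.52), with adjusted p = 4.9e-07 and adjusted p = 0.0994 with an estimated correlation. NEU1 rose by 1.87 ± 0.09 and acid ceramidase (ASAH1) by 1.45 ± 0.08. Heat shock genes fell in 14 of 16 cases and 1 rose (the same adjusted over the list alone, median -0.82), with adjusted p = 8.4e-07 and adjusted p = 0.108 with an estimated correlation. HSP90AA1 fell by 1.32 ± 0.08. FOXO target and quiescence genes rose in 17 of 23 cases and 2 fell (18 and 2 adjusted over the list alone, median 1.18), with adjusted p = 3.1e-05 and adjusted p = 0.108 with an estimated correlation. TXNIP rose by 3.13 ± 0.28 and CDKN1C by 2.60 ± 0.29. SRF and actin cytoskeleton genes fell in 15 of 27 cases and 2 rose (the same adjusted over the list alone, median -0.36), with adjusted p = 5.8e-04 and adjusted p = 0.259 with an estimated correlation. The tubulin TUBB6 fell by 1.37 ± 0.08. YAP and TEAD target genes fell in 14 of 22 cases and 2 rose (the same adjusted over the list alone, median -0.46), with adjusted p = 0.00135 and adjusted p = 0.214 with an estimated correlation. The receptor tyrosine kinase AXL fell by 1.85 ± 0.07 and CCN1 by 1.78 ± 0.27. NRF2 target genes rose in 14 of 22 cases and 2 fell (the same adjusted over the list alone, median 0.47), with adjusted p = 0.00129 and adjusted p = 0.0994 with an estimated correlation. HMOX1 rose by 2.07 ± 0.20.

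Interferon-stimulated genes rose in 11 of 20 cases at 24 h in 769-P and 1 fell (the same adjusted over the list alone, median 0.38), with adjusted p = 0.00771 and adjusted p = 0.187 with an estimated correlation. IFITM1 rose by 2.22 ± 0.21. Proximal tubule genes rose in 10 of 16 cases (10 adjusted over the list alone, median 0.49), with adjusted p = 0.0115 and adjusted p = 0.416 with an estimated correlation. DPP4 rose by 2.10 ± 0.20 and the kidney cadherin CDH16 by 1.17 ± 0.13. Integrin and focal adhesion genes fell in 15 of 26 cases and 5 rose (the same adjusted over the list alone, median -0.29), with adjusted p = 0.0256 and adjusted p = 0.143 with an estimated correlation. Caveolin 1 (CAV1) fell by 0.88 ± 0.10 and integrin beta 8 (ITGB8) rose by 2.64 ± 0.23. The ERK pathway feedback and immediate-early genes were not past the threshold as a list, and DUSP6 rose by 2.35 ± 0.15.

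**Figure D3:**
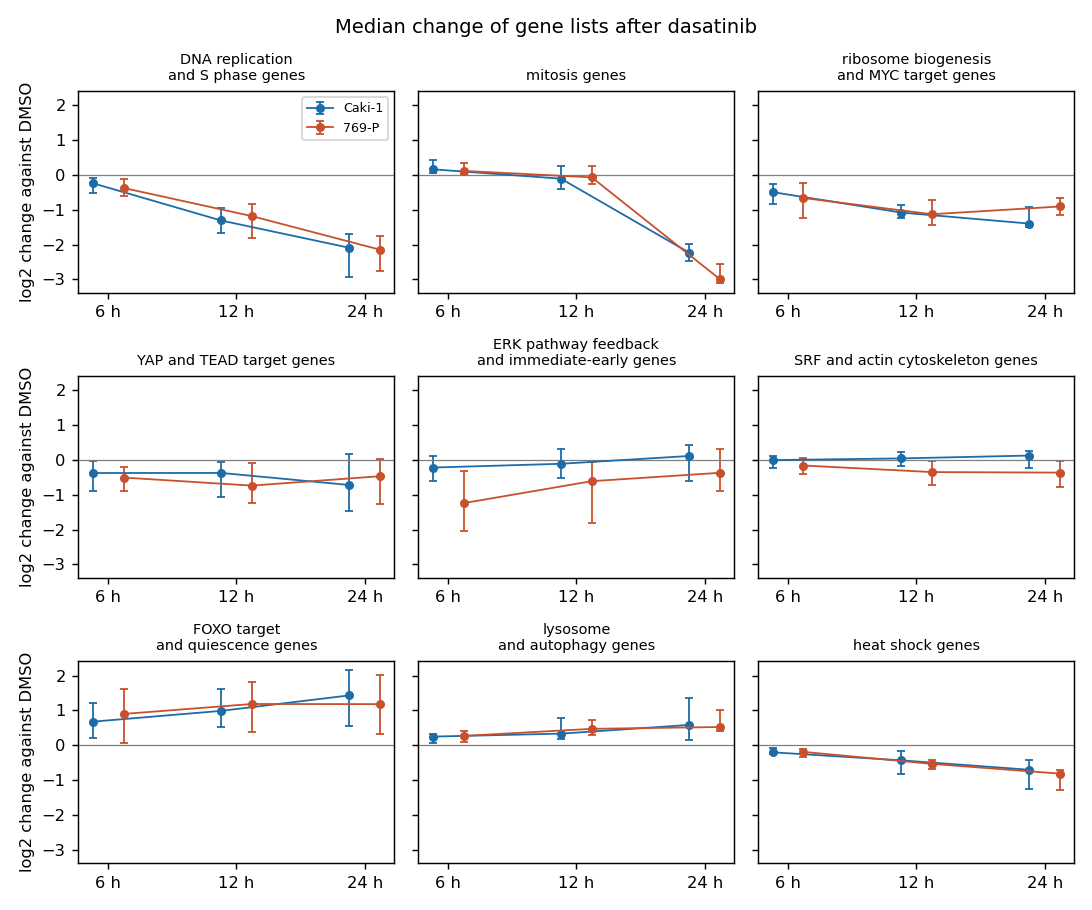
Median log2 change against DMSO (y axis) of 9 gene lists at 6, 12 and 24 h of dasatinib (x axis) in Caki-1 and 769-P, with bars from the lower to the upper quartile of the members. The mitosis list stays near 0 up to 12 h and reaches -2.24 in Caki-1 and -3.00 in 769-P at 24 h, while the replication list is already at -1.31 and -1.18 at 12 h.

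Of 186 tests of a list in these 6 comparisons, camera called 73 with its preset correlation. The NRF2 calls at 6 h and 12 h in 769-P were the only 2 that held with an estimated correlation. The other lists were not past the threshold in any of the 6 comparisons, with lowest adjusted p of 0.14 for p53 target genes, 0.0541 for fatty acid synthesis genes, 0.0541 for hypoxia target genes, and 0.165 for extracellular matrix genes. The lowest adjusted p was 0.357 for TGF-beta target genes, 0.212 for apoptosis genes, 0.36 for cytosolic ribosomal protein genes, 0.535 for epithelial genes and 0.264 for mesenchymal genes. Single members of these lists still moved: TP53INP1, a p53-induced stress protein, rose by 2.36 in Caki-1 and 1.98 in 769-P at 24 h, or 1.30 and 1.12 with the mean of all probe sets. PMAIP1, the pro-apoptotic protein NOXA, changed by -1.34 and -2.32. Dasatinib target kinase genes also stayed under the threshold as a list (lowest adjusted p = 0.467). SRC, YES1 and LYN were not past the threshold in any of the 6 comparisons, with changes from -0.27 for SRC at 6 h in Caki-1 to 0.23 for LYN at 12 h in 769-P. SRC at 6 h in Caki-1 had an adjusted p = 0.0708 and passed after median centring (adjusted p = 0.0471) and without replicate 1 of its treated group (-0.389, adjusted p = 0.00935). LYN at 12 h in 769-P had an adjusted p = 0.203 and passed only without replicate 3 of its treated group (0.398, adjusted p = 0.0261). Leukocyte and endothelial marker genes, which stand for cell types not in these cultures, had lowest adjusted p of 0.555 and 0.251. In 23 of the 186 tests, none of them a call, the median, the mean and the direction of the test did not share a sign.

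The changes of the 2 lines were then set side by side, to see how far the response was shared. At 6 h, 906 genes rose in both lines, where 236.8 would be expected by chance, and 1067 fell in both, where 242.7 would be. CCN1, FOSL1, CCND1 and EPHA2 fell and CDKN1C, AKR1C1 and MT1F rose in both lines at 6 h, 12 h and 24 h. At 12 h, 1818 rose and 1954 fell in both (695.6 and 666.3 expected), and at 24 h 2385 rose and 2284 fell in both (1194.4 and 894.6 expected). Genes with opposite calls numbered 84, 227 and 424 at the 3 times, where 482.5, 1363.3 and 2071.4 would be expected. The expected counts take every gene tested in both lines as equally likely to be called. Genes that are easier to call in both lines would raise these counts. Across the 11913 genes tested in both lines the changes had a Pearson r of 0.679, 0.725 and 0.757 and a Spearman correlation of 0.615, 0.684 and 0.674. These are correlations across genes, which are not independent replicates, and no p was computed for them.

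Whether a gene changed differently in the lines was asked with an interaction test, the Caki-1 change minus the 769-P change, over all 24 arrays. At 6 h the ERK pathway feedback and immediate-early genes stood out, with the change higher in Caki-1 for 17 of 27 and lower for 1 (19 and 2 adjusted over the list alone). Their median difference was 0.81 with adjusted p = 7.5e-20, which held with an estimated correlation at an adjusted p = 0.0218. EGR1 rose in Caki-1 and fell in 769-P (difference 2.27 ± 0.25, adjusted p = 7.7e-07). So did the ERK phosphatase DUSP5, which rose by 0.75 ± 0.17 and fell by 1.80 ± 0.15 (difference 2.55 ± 0.25). The feedback inhibitor SPRY2 rose by 0.53 ± 0.12 and fell by 1.04 ± 0.18 (difference 1.57 ± 0.23). MYC fell in both lines and further in 769-P (difference 2.38 ± 0.21). FGA, the fibrinogen alpha chain, rose in Caki-1 (difference 2.60 ± 0.24) and was too dim to be tested in 769-P alone, and RHOU rose in 769-P (-3.56 ± 0.21) and was too dim in Caki-1. With the mean of all probe sets of a gene the differences of EGR1 and FGA were 1.33 and 1.49, and with a pseudocount that of EGR1 was 1.48 and the change of DUSP5 in 769-P was -1.09. In all, 1041 of 12864 genes differed at 6 h, 473 with the higher change in Caki-1 and 568 with the lower.

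At 12 h, 2434 genes differed between the lines, 1115 higher and 1319 lower in Caki-1. RETREG1, a receptor for autophagy of the endoplasmic reticulum, rose in Caki-1 and was not past the threshold in 769-P (difference 3.005 ± 0.23). RHOU and KCNJ8 rose in 769-P (-3.41 ± 0.21 and -3.38 ± 0.31) and were too dim to be tested in Caki-1 alone. SRF and actin cytoskeleton genes differed in 15 of 27 cases, 14 of them higher in Caki-1 (15 higher and 1 lower adjusted over the list alone, median 0.40), with adjusted p = 6.1e-08 and adjusted p = 0.12 with an estimated correlation. At 24 h, 4629 genes differed, 1780 higher and 2849 lower in Caki-1. Mitosis genes fell further in 769-P in 23 of 29 cases (25 adjusted over the list alone, median 0.72), with adjusted p = 9.0e-11 and adjusted p = 0.391 with an estimated correlation. The difference of MKI67 was 1.29 ± 0.15. RBP4 rose in Caki-1 (3.90 ± 0.28) and SEMA5A and KCNJ8 rose in 769-P (-3.76 ± 0.25 and -3.57 ± 0.31), each too dim to be tested in the other line alone. COL5A2, a collagen chain, fell by 1.46 in Caki-1 and rose by 1.54 in 769-P. With the mean of all probe sets the 24 h differences of SEMA5A and COL5A2 were -2.48 and -1.05. Of the 4629 genes, 424 had opposite calls, 1684 were called the same way in both lines, 1322 only in Caki-1, 1117 only in 769-P and 82 in neither, where genes too dim to be tested in a line counted as not called there.

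The comparison of 24 h with 6 h of dasatinib, where the DMSO arrays enter the variance and the filter but not the change, asked what moved late. In Caki-1, 3485 genes were higher at 24 h and 3185 lower, and in 769-P, 3190 were higher and 2286 lower. SPC25, a kinetochore protein, fell by 3.55 ± 0.16 in Caki-1, and NDC80, its partner, by 3.85 ± 0.10 in 769-P. Mitosis genes fell in 29 of 29 cases in both lines (29 adjusted over the list alone, medians -2.45 and -3.03), with adjusted p = 2.1e-22 and adjusted p = 3.3e-39. With an estimated correlation these were adjusted p = 0.292 and adjusted p = 0.091. RBP4 rose by 3.09 ± 0.22 and ANXA13, an epithelial annexin, by 2.57 ± 0.30 in Caki-1, and DUSP6 rose by 2.83 ± 0.15 and CFI, complement factor I, by 3.08 ± 0.48 in 769-P. ERK pathway feedback and immediate-early genes rose from 6 h to 24 h in 16 of 27 cases in Caki-1, where 2 fell, and 17 of 26 in 769-P, where 1 fell (16 and 18 rises adjusted over the list alone, medians 0.32 and 0.70), with adjusted p = 0.0404 and adjusted p = 4.3e-05. The estimated correlation gave adjusted p = 0.66 and adjusted p = 0.292.

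Under DMSO the lines differed in 7550 of 12864 genes, 3700 higher and 3850 lower in Caki-1, 1895 of them by at least 2-fold. CXCL5, a chemokine that attracts neutrophils, was higher in Caki-1 by 9.01 ± 0.14, SRGN, the proteoglycan serglycin, by 9.37 ± 0.22 and GREM1, an antagonist of bone morphogenetic proteins, by 7.68 ± 0.18. PKIB, an inhibitor of protein kinase A, had a difference of -8.23 ± 0.13 and NEFL, a neurofilament chain, of -6.86 ± 0.15. Each of these 5 genes was too dim to be tested in the line with less of it, so the sizes are read against values near the background. Extracellular matrix genes were higher in Caki-1 in 18 of 24 cases and lower in 3 (the same adjusted over the list alone, median 1.45), with adjusted p = 2.4e-06, which held with an estimated correlation at an adjusted p = 0.00977. NF-kB target and inflammatory cytokine genes were higher in 17 of 25 cases and lower in 3 (19 and 3 adjusted over the list alone, median 0.72), with adjusted p = 1.0e-05 and adjusted p = 0.158 with an estimated correlation. NRF2 target genes were lower in 16 of 22 cases and higher in 1 (the same adjusted over the list alone, median -0.37), with adjusted p = 4.6e-04 and adjusted p = 0.158 with an estimated correlation. Among the other lists, those that passed with the preset correlation only were ATF4 and unfolded protein response, hypoxia and mesenchymal genes higher in Caki-1 and oxidative phosphorylation and epithelial genes lower, with adjusted p from 0.158 to 0.39 with an estimated correlation.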

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

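The splits of the arrays described here were fixed before the data were examined, while the tests of explanations were chosen after the results were seen. A difference between the lines in their response, found with the interaction test in limma over 24 arrays, drew attention to 1041 genes at 6 h, 2434 at 12 h and 4629 at 24 h. Values are the Caki-1 change minus the 769-P change on the log2 scale, and every one given for a gene had an adjusted p under 0.05.

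At 6 h, HS3ST1 (2.996), KCNJ15 (2.92), PDK4 (2.91), MT1G (2.62) and FGA (2.60) had the highest differences, and RHOU (-3.56), PCK1 (-3.47), ERBB3 (-2.90), GPR183 (-2.69) and C11orf96 (-2.55) the lowest. EGR1 (2.27), MYC (2.38), DUSP5 (2.55) and SPRY2 (1.57) were chosen after their values were seen. At 12 h the highest were GABRB1 (3.90), PDK4 (3.66), FGA (3.49), ABTB3 (3.035) and RETREG1 (3.005), and the lowest GPR183 (-4.49), MAF (-3.44), RHOU (-3.41), KCNJ8 (-3.38) and SEMA5A (-3.36). At 24 h the highest were GABRB1 (4.87), PDK4 (4.06), RBP4 (3.90), CDH1 (3.90) and FGA (3.77), and the lowest DNER (-4.78), MAF (-4.12), SEMA5A (-3.76), KCNJ8 (-3.57) and GPR183 (-3.56). CDK1 (0.835), MKI67 (1.29) and COL5A2 (-3.01) were chosen after their values were seen. KCNJ15, RHOU, PCK1, GPR183, C11orf96, GABRB1, ABTB3, MAF, KCNJ8 and SEMA5A were too dim to be tested in Caki-1 alone, and FGA, RBP4 and CDH1 in 769-P alone, so their differences and ranks rest partly on values near the background. With the mean of the probe sets of a gene the differences of MAF were -1.36 and -1.78 at 12 h and 24 h, those of SEMA5A -2.05 and -2.48, that of CDK1 0.395 and that of COL5A2 -1.05. For PDK4 it gave 1.65, 2.035 and 2.50 at the 3 times, for FGA 1.49 and 2.31 at 6 h and 12 h, for HS3ST1 1.63, for ERBB3 -1.36, for EGR1 1.33, for CDH1 2.095 and for DNER -3.115. With a pseudocount the differences of GABRB1 were 2.52 and 2.78, those of GPR183 -1.78, -2.975 and -2.24, and those of PCK1, C11orf96, EGR1 and DNER -2.255, -1.635, 1.48 and -2.925.

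Lists that differed between the lines had these median differences. At 6 h they were p53 target genes (0.212), SRF and actin cytoskeleton genes (0.163), ERK pathway feedback and immediate-early genes (0.807), NF-kB target genes (0.257), TGF-beta target genes (0.215), apoptosis genes (0.083) and ribosome biogenesis and MYC target genes (0.179). At 12 h they were SRF and actin cytoskeleton genes (0.401), ERK pathway genes (0.797), TGF-beta target genes (0.395), oxidative phosphorylation genes (-0.141) and mesenchymal genes (0.124). At 24 h they were mitosis genes (0.715), SRF and actin cytoskeleton genes (0.347), ERK pathway genes (0.274), hypoxia target genes (0.269), TGF-beta target genes (0.388), ribosome biogenesis and MYC target genes (-0.327), oxidative phosphorylation genes (-0.245) and mesenchymal genes (0.13). All had a camera adjusted p under 0.05 with the preset correlation. Only the ERK list at 6 h held with an estimated correlation (adjusted p = 0.0218), and the others had values from an adjusted p = 0.12 to an adjusted p = 0.738. With the replicate block the apoptosis list at 6 h had an adjusted p = 0.0518 and the mesenchymal list at 12 h an adjusted p = 0.107, and with quantile normalization the latter had an adjusted p = 0.0787.

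Probe sets that name several genes or none, 4305 in all, entered no comparison above. Many changed, though a smaller share than of the genes tested. In Caki-1, of 2374 tested, 480 passed at 6 h, 999 at 12 h and 1371 at 24 h. These were 20.2%, 42.1% and 57.8%, against 26.3%, 48.4% and 62.8% of genes. In 769-P, of 2364 tested, 482, 956 and 1180 passed. These were 20.4%, 40.4% and 49.9%, against 30.9%, 47.5% and 55.7% of genes.

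Regrouping of the arrays at random was tested by running each comparison on other splits of the same arrays. For the 3 differences between the lines, the labelled split, 1 of 100 drawn, gave the most calls. It gave 1041, 2434 and 4629 genes, against at most 63, 553 and 1868 in another split. The other splits mix arrays of both lines within a treatment, so real differences between the lines add to their spread and lower their calls. A cause that follows the groups could not be tested this way. For each comparison within a line and for the lines under DMSO only 10 splits exist. The labelled one gave the most calls, 1 of 10, which is too few to reach a share under 0.05, while every other split gave 0 calls within a line and at most 2 between the lines. Those splits mix arrays of both groups compared, so here too a real difference adds to their spread and lowers their calls.

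The fall of replication and mitosis genes at 24 h in both lines was weighed against technical causes. The array of 769-P with doubted RNA quality was not the source, since without it the mitosis median in 769-P was -3.032. Scaling by the authors moves genes of like level alike and so was not the whole source. The 58 members fell further than the 100 other genes nearest to each in DMSO level, with a median gap of -1.984 in Caki-1 and -2.556 in 769-P. A shift of all genes alike would be hidden by that scaling and could not be tested. Time in culture could not be told apart from the drug: the mitosis median of 769-P from 6 h to 24 h of dasatinib was -3.026, and the DMSO arrays carry no time. A loss of dividing cells under the drug and a slowing of growth as cultures fill both remain open.

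The further fall of mitosis genes in 769-P at 24 h did not come from the doubted array, since without it the median difference was 0.808. A signal floor in Caki-1 was argued against for 27 of 29 members, whose treated level was higher there, so their probe sets could read lower. The median DMSO levels were close, at 10.81 in Caki-1 and 10.72 in 769-P, so this count partly restates the further fall. The treated medians were 8.38 in Caki-1 and 7.68 in 769-P. Only 9 of 29 members had the higher DMSO level in Caki-1, and a higher starting level in 769-P was not tested for this list. The further fall of ERK genes in 769-P at 6 h did not rest wholly on a higher starting level in that line. Of 13 members with the higher DMSO level in Caki-1, 10 still had a difference above 0. Of 14 members with the higher DMSO level in 769-P, 12 did. Whether the size of the difference follows the starting level was not tested, so a partial share of it remains open. The further fall of ERK genes did not rest on the choice of probe set, with a median difference of 0.856 from the mean of all probe sets. Whether 769-P relies more on dasatinib-sensitive kinases for ERK signalling was not tested, since phosphorylation was not measured.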

How the results depend on the processing

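No called change of a named gene or list turned to the other direction under the alternatives run for it. Named genes were not run with other filters, with every probe set on its own or with other arrays in the fit. Lists were run only under the alternatives given for them below. The balance of rises and falls did turn: with median centring it was 3445 higher and 4023 lower in Caki-1 at 24 h, 1821 and 1950 in 769-P at 6 h, 2887 and 2953 there at 12 h, and 3140 and 3354 in Caki-1 from 6 h to 24 h, and with quantile normalization 3195 and 2805 in Caki-1 at 12 h. In Caki-1 it turned too at 12 h without the trend (2992 and 2970) and without DMSO replicate 1 (2982 and 2977), and at 24 h with the 60th percentile filter (3206 and 3423), with every probe set and at 2-fold. In 769-P it turned too at 6 h without the second 6 h array (1579 and 1590), and at 6 h and 12 h at 2-fold. From 6 h to 24 h it turned at 2-fold in both lines, to 316 and 565 in Caki-1 and 380 and 497 in 769-P, and for the differences at 12 h (284 and 219) and the lines under DMSO (1061 and 834). These comparisons were not divided into higher and lower beyond the 2 scalings and the 2-fold threshold. Counts of genes in each comparison stayed within 1.5 times their value under quantile normalization, median centring, other filters, the floor, the pseudocount, the mean of the probe sets of a gene, no intensity trend, other arrays in the fit, the replicate block and leaving out any 1 array, while those shared between the lines were tried with the 2 scalings and 2 filters alone. A threshold of 2-fold lowered the counts by construction: in Caki-1 to 124 higher and 159 lower at 6 h, 336 and 425 at 12 h and 670 and 936 at 24 h, and in 769-P to 227 and 232, 447 and 468, and 798 and 751. It gave 881 and 877 genes for 24 h against 6 h in Caki-1 and 769-P, 269, 503 and 855 for the differences, and 1895 for the lines under DMSO. Every probe set on its own raised the counts because more features were tested: in Caki-1 to 2979 higher and 3067 lower, 5689 and 6463, and 7957 and 8202, and in 769-P to 3488 and 3424, 5895 and 5700, and 7259 and 6959. It gave 13664 and 10983 for 24 h against 6 h, 1688, 4327 and 8841 for the differences, and 15905 for the lines under DMSO.

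Of 186 list tests camera called 73, which fell to 2 with an estimated correlation and was 120 with fry, where 2 of the 73 were lost; the cause was not tested. Quantile normalization gave 72, median centring 74, the replicate block 78 and leaving out the doubted array 74. The block added fatty acid synthesis genes (adjusted p = 0.00956) and receptor tyrosine kinase and ligand genes (adjusted p = 0.0475) at 6 h and hypoxia target genes at 24 h (adjusted p = 0.0339) in Caki-1, hypoxia target genes (adjusted p = 0.0323) and proximal tubule genes (adjusted p = 0.0473) from 6 h to 24 h there, and cholesterol biosynthesis genes at 12 h in 769-P (adjusted p = 0.0317), among comparisons whose numbers do not pair the arrays. Without the block these 6 had values from an adjusted p = 0.292 to an adjusted p = 0.754 with an estimated correlation.

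With the replicate block the counts were 1754 higher and 1920 lower, 3150 and 3185, and 4172 and 3812 in Caki-1, and 2356 and 2005, 3276 and 2979, and 3990 and 3181 in 769-P. It gave 6966 and 5873 for 24 h against 6 h, 1381, 2986 and 5173 for the differences and 7047 under DMSO, and changed no other call than those given in this closing section, the aryl hydrocarbon receptor list at 6 h in 769-P and TYROBP at 24 h in Caki-1. Without the doubted array, a choice made after seeing the data, 769-P had 2156 higher and 1881 lower at 6 h and 3164 and 2886 at 12 h.

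Of 801 results of named genes, 9 lost their call under quantile normalization, 6 under median centring, 3 with the pseudocount, 22 of 755 with the mean of the probe sets and 22 without the trend. The results missing from the 755 could not be tested there, since the mean of their probe sets lay under the filter. They are not counted as losses. Leaving out an array changed the side of 49. Dim genes limit the folds, since near the background the size of a change is less certain.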

Other observations

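The families in this paragraph were chosen after their values were seen. Each probe set used names 1 gene, but whether it also reads other members of its family was not tested. Of 9 metallothionein genes tested in Caki-1, 6 rose at 6 h, 7 at 12 h and 4 at 24 h, with 1 falling at 24 h, and MT1X rose by 1.84 at 6 h. Of 6 tested in 769-P, 2 rose at 6 h and at 12 h, and at 24 h 1 rose and MT2A fell by 1.19. The fibrinogen genes FGA and FGB rose by 2.71 and 1.77 at 6 h and by 3.801 and 3.749 at 24 h in Caki-1 (FGA at 6 h by 1.54 with the mean of its probe sets), while in 769-P FGB rose by 0.76 at 24 h only. AKR1C1, AKR1C2 and AKR1C3 rose in all 6 comparisons, with medians from 1.642 to 4.129.

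The order of the medians of replication and mitosis genes was looked at after the lists were seen and was not tested. The replication median minus the mitosis median was -0.40 in Caki-1 and -0.49 in 769-P at 6 h, -1.201 and -1.114 at 12 h, and 0.143 and 0.851 at 24 h. The flow of cells through the cycle was not measured.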
